A study of Rattus norvegicus with 12 samples.

How the data were processed

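Gene expression was measured on one-colour (Cy3) Agilent whole-genome rat arrays in NR8383 cells, a macrophage line derived from rat lung alveoli. Cells were exposed for 24 h to 1 of 6 multi-walled carbon nanotubes (MWCNTs), named MW1 to MW6 in the labels, or to the bovine serum albumin (BSA) vehicle of the same experiment. The labels describe MW1 and MW2 as rigid and needle-like and MW3 and MW4 as bent, all at 100 µg/mL, and MW5 and MW6 as straight and thin, both at 50 µg/mL. Each of the 12 groups (6 materials, 6 controls) holds 4 arrays, and per the labels each raw file is an independent biological replicate.

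The deposited scanner files hold linear spot intensity values. Per the file headers, these signals were extracted with Agilent Feature Extraction 10.7.3.1 for the MW1 and MW2 experiments and 12.0.3.1 for the other 4 experiments, whereas the submitters' processing notes name 12.0.3.1 for all. The intensity column used is already background-corrected, per the file headers, and is not scaled between arrays. The authors' deposited table of processed values is on a log2 scale. Its scale was checked against the scanner values, since no label states it: the table holds the mean of 4 arrays after 75th-percentile scaling, with each probe centred on the median of the 8 arrays of an experiment. Exposed-minus-control differences from the table followed those computed here with a correlation of at least 0.999999 across probes and a slope of 1. The medians of its exposed columns, from MW1 to MW6, were 0.133, 0.068, 0.034, 0.07, 0.059 and 0.207, and those of its control columns were -0.089, -0.014, -0.077, -0.025, -0.002 and 0.01. The table was used only as an alternative for fold changes.

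Each array's log2 intensity was taken relative to the 75th percentile of its 43379 non-control spots. Spots marked as outliers by the scanner software (7043 over all arrays) were left out, and no probe measurement was saturated. Replicate spots of a probe were averaged, which left 41012 probes. Gene names differed at 8131 spots between the 2 design versions in the files. The later names were taken and updated by transcript accession, symbol or synonym with a table of RefSeq genes (assembly GRCr8), which matched 18971, 2995 and 203 probes. The remaining 18843 probes kept the name in the files. A gene was represented by its probe with the highest mean over all 48 arrays, chosen among several probes for 4451 genes. Where other probes of a named gene disagree, their values are given. Probe positions are those in the files, on the rat assembly RGSCv3.4 (rn4). No annotation of that assembly was used, so exons and untranslated regions are not named.

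A gene was tested where its probe was well above background on all measured arrays (at least 3) of at least 1 of the 12 groups, which left 20990 genes and unnamed targets. A model with 1 mean per group was fitted to all 48 arrays with lmFit and eBayes of limma 3.58.1 (R 4.3.3, with version 1.17.8 of data.table). Each material was compared with its own control only. Further contrasts tested differences between 2 exposed-minus-control effects. P values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene passed at an adjusted p under 0.05. The count that was also at least 2-fold is given beside it, for differences as a 2-fold ratio of effects. All tests were two-sided. Changes are log2 differences with the standard error (SE) of the model, and levels are group means with the SD of 4 arrays. The number of arrays, 4 per group, limits the precision. Where a probe was well above background on none of the arrays of the dimmer group, the change is a lower bound ("at least N-fold"). That bound sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background. Where some arrays of a group measured the probe, their number is given, and no fold is given where both groups were below background.

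There were 28 fixed gene lists of pathways, macrophage genes, markers of other cell types and reference genes, each named where its result is given. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over all lists and the 6 materials (and, for differences, over all lists and contrasts), and again with an estimated correlation. The self-contained test fry was an alternative.

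Named genes followed a rule fixed before the data were examined. For each material these are the 8 largest rises and 8 largest falls among genes with a symbol that passed, changed at least 2-fold, had every exposed array beyond every control array and were well above background on all arrays of the brighter group. For each list, up to 4 passing members with the largest changes are named. For each difference of effects, the 5 largest positive and 5 largest negative differences among genes with a symbol that passed and were well above background on all 4 arrays of an exposed group are named. A few genes that this rule names are not reported by name, but they stay in every count. The gene lists, comparisons and alternatives were also fixed before the data were examined, except for leaving out 2 arrays that stood apart, which was chosen after seeing the data.

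Alternatives were normexp background correction (offset 50) of the mean and background signals, quantile normalization, no filter on dim probes, only probes well above background on all arrays compared, and the mean of a gene's probes. Further ones were a fit of only the arrays compared, a replicate block, trend and robust variance, array weights, the authors' deposited values, a 2-fold threshold, and each array left out in turn. Each group lies on its own slide (12 slides) and each experiment on its own scan day (6 days), so slide and group cannot be told apart and no fit with slide as a term could be made. Scan day is shared by a material and its control and leaves each comparison, but cannot be separated from experiment where 2 experiments are compared. The highest correlation between any 2 arrays was 0.9938 and no 2 arrays held identical values, so each material's controls are separate arrays. Other splits of the samples were counted for each contrast: all 35 for 4 against 4 arrays and 100 drawn with a fixed seed for the class contrasts.

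The fit was tested on 20990 simulated genes, with each gene's mean over all arrays and spread from the real data, and with 50 genes changed by each of 4 sizes in MW1 alone. For the MW1 comparison it called 46, 74, 94 and 100% of genes changed by a log2 of 0.5, 1, 2 and 3, and 8 unchanged genes. For MW1 minus MW2 these shares were 26, 50, 78 and 94%, and 9 unchanged genes. For needle-like minus bent, where MW1 is averaged with an unchanged MW2, they were 14, 44, 70 and 84%, and 4 unchanged genes. With camera, none of 27 unchanged simulated lists for MW1 had a p under 0.05, and a list shifted by a log2 of 0.5 had. Correlation between genes (up to 0.327 in real lists) was not simulated and so not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.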

Results

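Messenger RNA of NR8383 rat alveolar macrophages was measured on 48 arrays, 4 for each of 6 MWCNTs and 4 for each BSA control. Exposure lasted 24 h, at 100 µg/mL for needle-like MW1 and MW2 and bent MW3 and MW4, and at 50 µg/mL for thin straight MW5 and MW6. The 75th percentile of the signal lay between 268.4 and 913.1 per array, and between 18249 and 29195 probes were well above background. The median SD of a gene between the 4 arrays of a group was 0.0707 (MW3) to 0.187 (MW6) on the log2 scale. MW5 array 3 had the fewest probes well above background and MW6 array 4 the lowest mean correlation with its group, as given below. Levels are log2 intensities relative to the array's 75th percentile, given as mean ± SD (n = 4 arrays). Comparisons ask which genes differ between cells with a material and its own vehicle control, and later ones whether 2 materials or shape classes differ in that effect. For each gene named below for its size of change with a material, all 4 exposed arrays lay beyond all 4 control arrays. Each group lay on its own slide, so slide and group cannot be told apart.

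**Figure D1:**
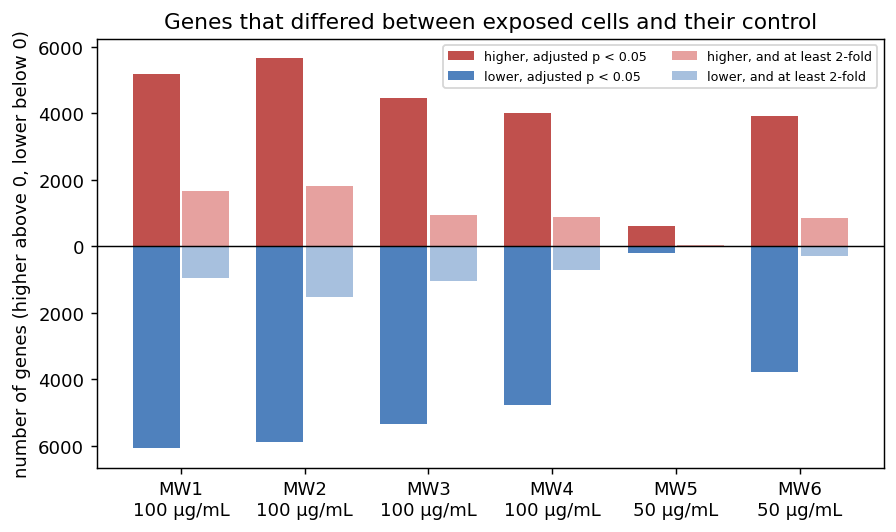
Numbers of genes that differed between exposed cells and their own control (limma, n = 4 arrays per group), per material with its dose on the horizontal axis. Bars above 0 count higher genes and bars below 0 count lower genes, dark at adjusted p under 0.05 and pale where the change was also at least 2-fold. MW2 changed 11520 genes and MW5 811.

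With MW1, Mmp9, a secreted gelatinase, rose 81.8-fold, from a log2 level of -3.65 ± 0.2 to 2.7 ± 0.24 (log2 change 6.35, SE 0.1, adjusted p = 9.82e-37; probe A_44_P501112 on chromosome 3, from 155992463 to 155992522, rn4). Sbsn, a secreted protein known from epidermis, rose 74.4-fold (SE 0.14 on the log2 scale). Acod1, which makes itaconate in activated macrophages, was at least 23.9-fold higher, the adaptor Lat2 at least 31.2-fold and the carboxylesterase Ces1c at least 44.2-fold. The probes of these 3 genes were not well above background on any control array. Nckap1, of the actin-regulating WAVE complex, and the actin-binding Xirp1 were higher by a log2 of 6.97 and 6.94, with 1 of 4 control arrays well above background. Among the falls, the macrophage lectin Clec10a was 6.94-fold lower (log2 1.93 ± 0.09 to -0.86 ± 0.2, adjusted p = 2.06e-24), Fgl2 6.32-fold and the glycogen synthase Gys2 5.92-fold. The succinate receptor Sucnr1 was lower by a log2 difference of -3.46, with 2 of 4 exposed arrays well above background. Below background on all exposed arrays were Spata46 (at least 3.7-fold lower), Lef1 (at least 1.9-fold), Tfap4 (at least 1.83-fold) and the T cell co-receptor Cd8a (at least 1.57-fold). Other probes disagreed for Ces1c (log2 change 0.98), Fgl2 (-2.04 to 0.55) and Lef1 (0.97). Of all genes tested, 5166 were higher and 6064 lower, of which 1664 and 962 changed at least 2-fold. With normexp background, 13 of the 16 changes under the naming rule were smaller by over 1.5 times (Mmp9 5.18, Sbsn 5.36, Acod1 2.33), and Lef1 (-0.4), Cd8a (-0.36) and Tfap4 (-0.37) no longer passed. With the mean of a gene's probes, Lef1 did not pass either (-0.77), and Ces1c (3.62) and Fgl2 (-1.38) were smaller by over 1.5 times.

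Of 31 chemokine and cytokine genes, 20 rose and 4 fell with MW1 (median log2 change 1.16, adjusted p = 5.34e-09). Ccl4 rose 24-fold, the neutrophil attractant Cxcl2 18-fold and the interleukin 1 antagonist Il1rn 16-fold. Of 24 NF-kB feedback and inflammasome genes, 19 rose and 3 fell (median 1.61, adjusted p = 2.89e-12), or 4 lower when adjusted over the list alone. They included Birc3 (8.13-fold higher) and Icam1 (5.52-fold). Of 22 matrix and growth factor genes, 14 rose and 3 fell (median 0.73, adjusted p = 2.73e-06), with Serpinb2 higher by a log2 of 5.89 (3 of 4 control arrays well above background) and Mmp10 at least 12.8-fold. Of 24 glycolysis and hypoxia genes, 20 rose and none fell with limma (1 at an unadjusted p under 0.05; median 0.62, adjusted p = 3.13e-10), among them the lactate transporter Slc16a3 (8.68-fold) and Hk2 (3.12-fold). The 24 cholesterol synthesis genes went both ways, 7 higher and 7 lower (median 0, adjusted p = 0.776): Lss rose 1.63-fold, and Tm7sf2 fell 1.7-fold. All 29 mitosis genes (median -0.95, adjusted p = 4.26e-17) and all 30 DNA replication genes (median -0.92, adjusted p = 1.73e-17) fell, with Spc25 2.65-fold and the replication licensing gene Cdc6 2.65-fold lower. Counts adjusted over the list alone equalled those over all genes for the other lists. Normexp background gave smaller log2 changes for Birc3 (2.36, from 3.02), Serpinb2 (4.04) and Mmp10 (2.02).

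MW2 raised Inhba, a subunit of activin A, 129-fold, from -2.28 ± 0.2 to 4.72 ± 0.1 (log2 change 7.01, SE 0.12, adjusted p = 9.89e-35; probe A_42_P839593 on chromosome 17, from 57240473 to 57240532, rn4). Xirp1 rose 92.6-fold (SE 0.25 on the log2 scale). Acod1 was at least 75.6-fold higher, Ces1c at least 102-fold, the collagen prolyl hydroxylase P4ha3 at least 54.6-fold, the natriuretic peptide gene Nppb at least 44.7-fold, the adenosine receptor Adora2a at least 27.5-fold and the matrix protease Mmp10 at least 18.1-fold, with no control array well above background. Abcd2, a peroxisomal transporter of very long fatty acids, was 14.3-fold lower (1.12 ± 0.12 to -2.72 ± 0.23, adjusted p = 5.02e-29), and Coq8a, needed for coenzyme Q, and Gys2 were each 12.3-fold lower. Afdn, which encodes the junction protein afadin, fell at least 25.5-fold, Sucnr1 at least 17.3-fold, Spata46 at least 7.73-fold, the phosphodiesterase Pde9a at least 7.37-fold and the kinase Bmx at least 3.21-fold, all below background on the 4 exposed arrays. Other probes gave smaller log2 changes for Ces1c (1.3), P4ha3 (0.23) and Afdn (-0.49 to -0.2). In total, 5650 genes were higher and 5870 lower, of which 1799 and 1527 changed at least 2-fold. With normexp background, 15 of these 16 changes were smaller by over 1.5 times (Inhba 6.42, Acod1 4.08, Abcd2 -3.21). With the mean of a gene's probes, Ces1c (4.09), P4ha3 (3.79), Adora2a (5.81) and Afdn (-2.23) were.

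Of the chemokine and cytokine genes, 19 of 31 rose and 4 fell with MW2 (median 1.54, adjusted p = 9.7e-06). Cxcl2 rose 26.6-fold, Ccl4 21.9-fold and Cxcl1 at least 5.8-fold. Of 24 NF-kB genes, 17 rose and 5 fell (median 1.53, adjusted p = 1.08e-06), among them Birc3 (6.4-fold) and the nitric oxide synthase Nos2 (at least 5.21-fold). Matrix and growth factor genes rose in 12 of 22 cases and fell in 2 (median 0.63, adjusted p = 3.63e-05), with Mmp14 at least 12.2-fold higher and Serpinb2 by a log2 of 5.92 (1 of 4 control arrays well above background). Glycolysis genes rose in 21 of 24 cases and none fell with limma (0 at an unadjusted p under 0.05; median 0.85, adjusted p = 2.89e-12), with Slc16a3 23.8-fold higher. Cholesterol synthesis genes rose in 18 of 24 cases and fell in 2 (median 0.86, adjusted p = 1.03e-07), with Sqle 4.46-fold and Insig1 3.5-fold higher. All 29 mitosis genes (median -1.16, adjusted p = 2.75e-17) and all 30 DNA replication genes (median -1.26, adjusted p = 6.75e-19) fell, with Kif2c 3.53-fold, Top2a 3.14-fold and Mcm10 5.03-fold lower. Adjusted over the list alone, each of these counts was the same. Normexp background gave smaller log2 changes for Birc3 (2.04, from 2.68), Mcm10 (-1.73, from -2.33), Serpinb2 (3.89), Cxcl1 (1.27), Nos2 (1.12) and Mmp14 (1.8).

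MW3 raised Inhba 43.5-fold (-1.35 ± 0.32 to 4.09 ± 0.12, adjusted p = 3.11e-30), Xirp1 35.5-fold and Sbsn 29.8-fold, with SEs of 0.12, 0.25 and 0.14 on the log2 scale. The dopamine transporter gene Slc6a3 was at least 144-fold higher (-5.98 ± 0.54 in controls, below background on all 4, to 1.54 ± 0.11), the bicarbonate transporter Slc4a8 at least 33.3-fold, Nppb at least 23.3-fold, the matrix glycoprotein Fbln1 at least 15.6-fold and the ubiquitin ligase Trim63 at least 6.67-fold. The amino acid transporter Slc36a2 was 13.5-fold lower (adjusted p = 7.47e-24), Gys2 10.8-fold, Afdn 9.58-fold and the lectin-like Clec2l 8.2-fold. Sucnr1 was lower by a log2 difference of -3.6, with 1 of 4 exposed arrays well above background. Bmx fell at least 4.38-fold, the phosphoinositide kinase subunit Pik3r3 at least 1.85-fold and the cytokine Il16 at least 1.54-fold. Other probes gave smaller log2 changes for Fbln1 (0.04), Afdn (-0.6 to -0.11) and Pik3r3 (-1.26 to -0.95). MW3 raised 4468 genes and lowered 5345 (3884 and 3529 with normexp background), of which 943 and 1037 changed at least 2-fold. With normexp background, 12 of these 16 changes were smaller by over 1.5 times (Slc6a3 4.43, Gys2 -2.03, Slc36a2 -2.27), and Pik3r3 (-0.36) and Il16 (-0.36) no longer passed. With the mean of a gene's probes, Fbln1 (2.74), Trim63 (3.9), Gys2 (-2.84), Afdn (-1.32) and Pik3r3 (-1.7) were smaller by over 1.5 times.

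Chemokine and cytokine genes rose in 18 of 31 cases and fell in 4 with MW3 (median 0.51, adjusted p = 0.00029), a call lost at an adjusted p = 0.0501 with an estimated correlation. Ccl4 rose 12.5-fold, oncostatin M (Osm) 5.4-fold and Il1rn 5.06-fold. NF-kB genes rose in 16 of 24 cases, or 17 adjusted over the list alone, and fell in 5 (median 0.62, adjusted p = 5.99e-05), with Acod1 16-fold, Nos2 5.86-fold and Birc3 4.59-fold higher. Matrix genes rose in 15 of 22 cases and fell in 1 (median 0.64, adjusted p = 1.56e-06), with Mmp10 10.1-fold and Serpinb2 9.67-fold higher. Glycolysis genes rose in 19 of 24 cases and fell in 1 (median 0.61, adjusted p = 6.64e-10), with Hk1 15.9-fold and Slc16a3 3.33-fold higher. Cholesterol synthesis genes rose in 21 of 24 cases and none fell with limma (0 at an unadjusted p under 0.05; median 1.1, adjusted p = 1.11e-17), with Insig1 3.75-fold and Msmo1 3.18-fold higher. All 29 mitosis genes (median -0.85, adjusted p = 5.73e-18) and 28 of 30 DNA replication genes (median -0.7, adjusted p = 2.21e-13) fell, with Ccnb2 2.56-fold and Mcm10 2.37-fold lower. For lists with no second count, adjusting over the list alone gave the same counts. Normexp background gave smaller log2 changes for Hk1 (2.21, from 3.99, and 3.4 with the mean of its probes), Acod1 (2.42, from 4), Nos2 (1.5, from 2.55), Osm (1.73, from 2.43) and Serpinb2 (2.47, from 3.27).

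MW4 raised the kinase gene Cdkl4 29.7-fold, Inhba 26.2-fold and Dmkn, the secreted epidermal protein dermokine, 25.4-fold (0.79 ± 0.07 to 5.46 ± 0.05, log2 change 4.66, SE 0.07, adjusted p = 1.42e-37; probe A_43_P16413 on chromosome 1, from 85828638 to 85828697, rn4). Nppb was at least 28.1-fold higher and Slc6a3 at least 10.8-fold. Lat2 rose by a log2 of 4.92, with 2 of 4 control arrays well above background, and Ccn5 (4.87) and the prolactin family gene Prl7a3 (4.68) with 1 of 4. Sucnr1 was 10.2-fold lower (adjusted p = 3.19e-19), Gys2 9.08-fold, the clotting factor gene Vwf 8.9-fold (another probe rose by 1.31) and Angptl4, an inhibitor of lipoprotein lipase, 8.26-fold. Slc36a2 fell at least 5.7-fold, the apolipoprotein gene Apoa4 at least 3.63-fold and Lef1 at least 3.06-fold (another probe 0.22), and the olfactory receptor gene Or5b123b had a log2 difference of -2.91 with 2 of 4 exposed arrays well above background. MW4 raised 4019 genes and lowered 4769, of which 880 and 718 changed at least 2-fold. With normexp background, 13922 genes passed, 68.8% of them higher against 45.7%, and the median of all genes moved to 0.257; 15 of the 16 changes were smaller by over 1.5 times (Inhba 4.01, Cdkl4 2.91, Gys2 -2.34), Slc36a2 (-0.05) and Or5b123b (-0.47) no longer passed, and Lef1 (0.18) and Apoa4 (0.1) turned positive. With the mean of a gene's probes, Vwf no longer passed (-0.92) and Lef1 was -1.61, and without MW4 control array 1 Apoa4 was -2.45.

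The 31 chemokine and cytokine genes did not move one way with MW4, with 9 higher and 9 lower (median 0.04, mean 0.03, but direction down in the test, adjusted p = 0.944). Osm rose 8.13-fold, while the interferon-induced chemokine Cxcl10 fell 7.45-fold, Ccl12 6.23-fold and interleukin 1 beta (Il1b) 5.61-fold. NF-kB genes also went both ways, 11 higher and 9 lower, or 10 lower adjusted over the list alone (median 0.17, adjusted p = 0.309), with Acod1 at least 5.7-fold and Nfkbib 2.48-fold higher. Matrix genes rose in 14 of 22 cases, or 15 adjusted over the list alone, and fell in 2 (median 0.47, adjusted p = 7.4e-06), with transglutaminase Tgm2 13-fold, the macrophage elastase Mmp12 10.1-fold and Mmp10 9.97-fold higher. Glycolysis genes rose in 21 of 24 cases and none fell with limma, nor did any cholesterol synthesis gene (0 of either at an unadjusted p under 0.05; glycolysis median 0.75, adjusted p = 2.09e-16), with Slc16a3 16.9-fold and Hk2 3.38-fold higher. Cholesterol synthesis genes rose in 22 of 24 cases, or 23 adjusted over the list alone (median 0.88, adjusted p = 1.11e-17), with Sc5d 2.73-fold and Insig1 2.47-fold higher. Mitosis genes fell in 28 of 29 cases (median -0.64, adjusted p = 1.1e-13) and DNA replication genes in 28 of 30, or 29 adjusted over the list alone (median -0.74, adjusted p = 1.86e-16), with Mcm10 2.78-fold, Ccne2 2.49-fold and Ttk 2.11-fold lower. Normexp background gave smaller log2 changes for Osm (1.69, from 3.02), Ccl12 (-1.8, from -2.64), Mmp10 (1.73, from 3.32) and Acod1 (1.13).

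MW5 changed fewer genes and by less. Inhba rose 3.74-fold (-1.01 ± 0.1 to 0.89 ± 0.19, log2 change 1.9, SE 0.12, adjusted p = 6.85e-14), Sbsn 3.33-fold, Xirp1 2.78-fold, the protease inhibitor Serpinb2 2.75-fold, Mmp10 2.69-fold, Spmip7 2.5-fold and Dmkn 2.38-fold (4.87 ± 0.06 to 6.13 ± 0.06, adjusted p = 8.94e-17). Slc6a3 rose by a log2 of 1.94, with 1 of 4 control arrays well above background. The rule named 2 falls, the immediate early gene Fos (2.14-fold, 1.79 ± 0.14 to 0.69 ± 0.21, adjusted p = 0.000408) and Ccdc142 (log2 difference -1.11, 3 of 4 exposed arrays well above background, adjusted p = 0.00731). Of all genes, 602 were higher and 209 lower, of which 44 and 29 changed at least 2-fold. With normexp background 194 genes passed, of which 186 were also called above, and Slc6a3 (0.64) and Ccdc142 (-0.21) no longer passed, while Spmip7 was smaller (0.61); with array weights 2268 passed, and quantile normalization gave 59.3% higher calls against 74.2%. Ccdc142 also missed the threshold in a fit of only the 8 arrays and without MW5 control array 1 (-0.74) or MW5 array 3 (-0.87), and the count was 468, 517 and 488 without control arrays 1 and 2 and MW5 array 4, and 741 without MW5 array 3.

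Cholesterol synthesis and glycolysis genes rose as groups with MW5. Of 24 cholesterol synthesis genes, 16 rose, or 21 adjusted over the list alone, and none fell with limma (0 at an unadjusted p under 0.05; median 0.39, adjusted p = 6.72e-29), with Acat2 1.54-fold, Idi1 1.47-fold and Msmo1 1.44-fold higher, where Acat2 did not pass with the mean of a gene's probes nor Msmo1 with normexp background. Of 24 glycolysis genes, 14 rose and none fell (1 at an unadjusted p under 0.05; median 0.24, adjusted p = 1.18e-15), with 15 higher and 1 lower adjusted over the list alone, and Slc16a3 was 1.67-fold and Slc2a1 1.34-fold higher. Matrix genes rose in 6 of 22 cases and none fell (1 at an unadjusted p under 0.05; median 0.18, adjusted p = 8.76e-06), with 7 higher and 1 lower adjusted over the list alone, and Tgm2 was 1.6-fold and Mmp12 1.47-fold higher. NF-kB genes rose in 5 of 24 cases and fell in 1 (median 0.17, adjusted p = 0.000616), with 9 and 2 adjusted over the list alone, and Nos2 was 2.11-fold and Icam1 1.37-fold higher; this list did not pass with normexp background (adjusted p = 0.0543). Of 31 chemokine and cytokine genes, 2 rose and 2 fell (median 0.14, adjusted p = 0.116), with 3 higher adjusted over the list alone: Ccl4 rose 1.49-fold. Of 29 mitosis genes 1 fell, with 3 lower adjusted over the list alone (median -0.07, adjusted p = 0.0018, and adjusted p = 0.126 with an estimated correlation). None of 30 DNA replication genes passed with limma (1 higher and 2 lower at an unadjusted p under 0.05), and 1 rose and 1 fell adjusted over the list alone (median -0.02, adjusted p = 0.618, and 0.0256 with normexp background).

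MW6, at the dose of MW5, raised Inhba 21.5-fold (-0.02 ± 0.1 to 4.4 ± 0.21, log2 change 4.43, SE 0.12, adjusted p = 4.66e-27). Slc4a8 was at least 14-fold higher, Fbln1 at least 11.3-fold, the elongation factor gene Eef1a2 at least 8.76-fold, the prolactin family gene Prl8a9 at least 6.09-fold and the adhesion gene Mpzl2 at least 5.97-fold, each below background in controls, with other probes at 1.29 for Fbln1 and 1.05 to 1.28 for Mpzl2. Slc6a3 rose by a log2 of 4.49 with 1 of 4 control arrays well above background, and Nppb by 4.45 with 3 of 4. Afdn was 6.34-fold lower (other probes 0.37 to 0.83), Gys2 4.78-fold, Pdcd4, an inhibitor of translation, 4.31-fold (1.74 ± 0.09 to -0.37 ± 0.07, adjusted p = 2.38e-26), Abcd2 4-fold and the lysosomal transporter Slc46a3 3.87-fold. Sucnr1 (-2.63) and Slc36a2 (-2.2) were lower with 3 of 4 exposed arrays well above background. Of all genes, 3918 were higher and 3781 lower, of which 856 and 297 changed at least 2-fold. The count was 4702 with normexp background (2230 higher, 2472 lower), where 14 of the 16 changes under the naming rule were smaller by over 1.5 times (Slc4a8 1.34, Gys2 -1.54, Abcd2 -1.38) and Prl8a9 (0.66) no longer passed, and 4512 in a fit of only these 8 arrays; quantile normalization gave 39% higher calls against 50.9%. With the mean of a gene's probes Afdn (-0.49) no longer passed and Fbln1 (3.17) and Mpzl2 (2.22) were smaller, Prl8a9 (3.51) and Mpzl2 (3.4) were smaller with quantile normalization, and Slc6a3 was 5.28 and 3.88 without MW6 control arrays 1 and 3.

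Chemokine and cytokine genes rose in 19 of 31 cases and fell in 3 with MW6 (median 0.68, adjusted p = 2.63e-05), with 20 higher adjusted over the list alone. Osm rose 5.74-fold and Ccl4 3.29-fold. NF-kB genes went both ways, 11 of 24 higher and 6 lower, or 7 lower adjusted over the list alone (median 0.17, adjusted p = 0.242, but 0.0263 with normexp background and 0.0382 with quantile normalization), with Acod1 6.35-fold and Nos2 2.92-fold higher. Matrix genes rose in 13 of 22 cases, or 14 adjusted over the list alone, and fell in 2 (median 0.53, adjusted p = 3.24e-06), with Mmp10 10.4-fold and Mmp12 4.83-fold higher. Glycolysis genes rose in 19 of 24 cases, or 20 adjusted over the list alone, and none fell with limma, nor did any cholesterol synthesis gene (0 of either at an unadjusted p under 0.05; glycolysis median 0.52, adjusted p = 1.82e-12), with Slc16a3 2.46-fold and Hk2 1.99-fold higher. Cholesterol synthesis genes rose in 21 of 24 cases (median 0.64, adjusted p = 3.44e-16), with Msmo1 2.09-fold and Sc5d 1.93-fold higher. Mitosis genes fell in 28 of 29 cases (median -0.74, adjusted p = 4.87e-26) and DNA replication genes in 22 of 30 (median -0.33, adjusted p = 4.62e-09), with Ccnb2 2.26-fold and Mcm10 1.77-fold lower. Normexp background gave smaller log2 changes for Osm (1.15, from 2.52), Acod1 (1.32, from 2.67) and Nos2 (0.91, from 1.55).

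**Figure D2:**
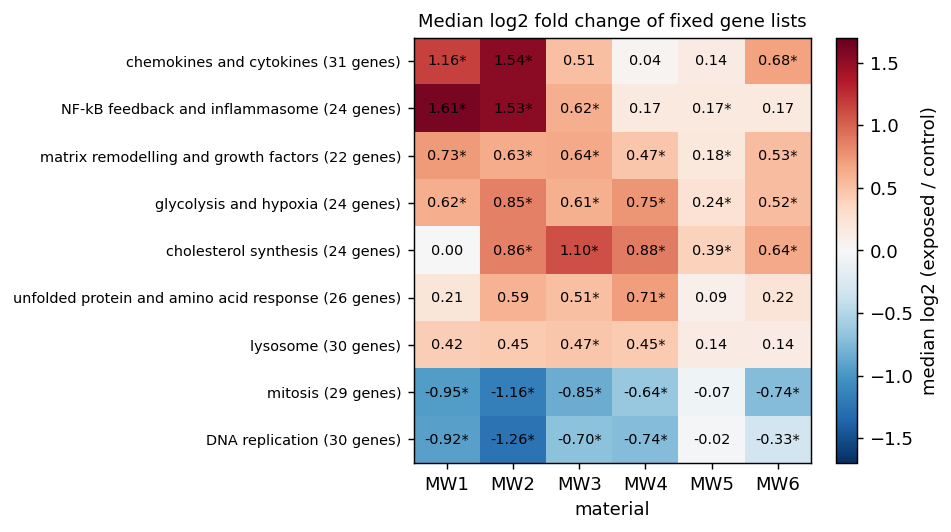
Median log2 fold change (exposed over control, colour and printed value) of 9 fixed gene lists, in rows with the number of genes tested, for the 6 materials in columns. An asterisk marks an adjusted p under 0.05 with an estimated correlation. The mitosis list ranges from -1.16 with MW2 to -0.07 with MW5, and the cholesterol synthesis list from 0 with MW1 to 1.1 with MW3.

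MW1 and MW2, both needle-like and at the same dose, differed in their effects at 4715 genes, 2284 with a higher effect of MW1 and 2431 with a higher effect of MW2 (457 and 554 at least 2-fold). Mmp9 rose more with MW1 (log2 changes 6.35 and 3.46, difference 2.89, SE 0.13, adjusted p = 6.37e-19), but most of this lay between the controls (-3.65 ± 0.2 and -1.27 ± 0.14, against 2.7 ± 0.24 and 2.19 ± 0.03 in exposed cells). Cholesterol synthesis genes had the lower effect with MW1 in 21 of 24 cases and, in limma, the higher in none (0 at an unadjusted p under 0.05; median difference -0.65, adjusted p = 2.16e-22), while the MW1 and MW2 controls were at -0.32 and -1.05 relative to the median of the other controls. DNA replication genes fell less with MW1, 17 of 30 with a higher and 1 with a lower effect (median 0.34, adjusted p = 8.67e-08). The other named differences included groups below background. Afdn (difference 3.63) was below background on all MW2 arrays. Acss1 (3.51), Prr15 (3.21), Tm4sf20 (2.62), Arc (-5.04), Rhpn2 (-4.97), Slc35e4 (-3.86) and Cd86 (-2.95) were below background in all arrays of at least 1 control. With normexp background 2504 genes passed and all 10 differences under the naming rule were smaller by over 1.5 times (Mmp9 2.03), with Tm4sf20 (0.52) and Cd86 (-0.06) no longer passing. Afdn (1.77), Rhpn2 (-2.17) and Cd86 (-1.26) were smaller with the mean of a gene's probes, and Rhpn2 was -5.8 with quantile normalization and -4.06 without MW1 control array 3.

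MW3 and MW4, both bent and at the same dose, differed at 3567 genes, 1909 with a higher effect of MW3 and 1658 with a higher effect of MW4, a balance that turned at 2-fold (193 and 355) and with quantile normalization (1502 and 1930). Chemokine and cytokine genes had the higher effect with MW3 in 14 of 31 cases and the lower in 2 (median difference 0.84, adjusted p = 1.46e-08), and NF-kB genes in 12 of 24 and 2 (median 0.33, adjusted p = 4.51e-07). Mitosis genes fell more with MW3, 9 of 29 lower and none higher with limma (0 at an unadjusted p under 0.05; median -0.25, adjusted p = 7.2e-06). Markers of fibroblasts and smooth muscle had the lower effect with MW3 in 3 of 6 cases and the higher in none with limma (0 at an unadjusted p under 0.05; median difference -0.53, adjusted p = 0.0216, and adjusted p = 0.0401 with an estimated correlation). Trim63 (4.43), Neu2 (3.95), Arc (3.86), Ablim1 (3.56) and Cd22 (3.54) were well above background on all 4 MW3 arrays and on none of the MW4 arrays or of either control. The opposite differences were Ccn5 (-3.81) and Nos3 (-2.82), not well above background on any MW3 or MW3 control array, and Stk32a (-3.19), Scd2 (-3.14) and Tph1 (-3.14), which were well above background on at most 1 array of the MW4 control. Under normexp background all 10 were smaller by over 1.5 times (Ccn5 -1.31, Scd2 -1.33) and the 5 positive ones did not pass (Trim63 0.29, Neu2 0.25, Arc 0.54, Ablim1 0.19, Cd22 0.13), while array weights gave 6729 genes. With the mean of a gene's probes Scd2 did not pass (-0.97) and Trim63 (3.77), Cd22 (2.76) and Tph1 (-2.25) were smaller, and Tph1 was -1.71 without MW4 array 4 and missed the threshold in a fit of only the arrays compared.

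MW5 and MW6, both thin, straight and at 50 µg/mL, differed at 4348 genes, with 2531 higher and 1817 lower effects of MW5, but 144 and 572 at 2-fold. Mitosis genes fell with MW6 and differed from MW5 in 25 of 29 cases (median difference 0.72, adjusted p = 5.2e-26), and DNA replication genes in 15 of 30 (median 0.33, adjusted p = 1.8e-08). Chemokines and cytokines had the lower effect with MW5 in 13 of 31 cases and the higher in 2 (median -0.46, adjusted p = 6.73e-05). Coq8a fell with MW6 and not detectably with MW5 (log2 changes -1.93 and -0.11, difference 1.83, SE 0.11, adjusted p = 6.06e-16), and so did Abcd2 (1.74), Sucnr1 (2.46), Afdn (2.3) and Slc36a2 (1.79). Mpzl2 (-4.6), Slc4a8 (-3.45), Stmn4 (-3.3), Eef1a2 (-3.3) and Vwa2 (-3.18) had the higher effect of MW6 and were below background on all MW6 control arrays. With normexp background 1933 genes passed and 8 of the 10 differences were smaller by over 1.5 times (Sucnr1 0.91, Slc4a8 -1.06), with Mpzl2 (-0.66), Stmn4 (-0.69), Eef1a2 (-0.76) and Vwa2 (-0.41) no longer passing. Afdn did not pass with the mean of a gene's probes (0.5), nor Vwa2 in a fit of only the arrays compared. Mpzl2 was -1.95 with that mean, quantile normalization gave -3.64 for Mpzl2, -2.84 for Slc4a8 and -2.58 for Vwa2, and without MW5 control array 4 Mpzl2 was -3.89 and without MW5 control array 3 Vwa2 was -2.43.

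Needle-like and bent materials, all at 100 µg/mL, were compared through the mean effects of MW1 and MW2 and of MW3 and MW4. The effects differed at 7283 genes, 3442 higher and 3841 lower with needle-like materials, but 961 and 139 at 2-fold. P values of class contrasts treat arrays as replicates and do not measure the spread between a class's 2 materials. The lipopolysaccharide co-receptor gene Cd14 rose by a log2 of 5.36 and 4.42 with MW1 and MW2 and by 0.88 and 0.93 with MW3 and MW4 (difference 3.99, SE 0.09, adjusted p = 2.93e-30; chromosome 18, from 29374990 to 29375049, rn4). Control levels of Cd14 were -0.38 to -0.05 (MW1), -0.25 to 0.01 (MW2), 1.94 to 2.3 (MW3) and -1.99 to -1.79 (MW4). Part of its gap to MW3 thus lay in the controls. Mmp9 had log2 changes of 6.35 and 3.46 against 1.48 and -0.17, the last of which did not pass (difference 4.26, SE 0.1, adjusted p = 2.93e-30), but its controls also differed, from -3.65 ± 0.2 (MW1) to 2.75 ± 0.15 (MW3), and its level with MW3 (4.23 ± 0.05) was above that with MW1. Adora2a (4.74), Ces1c (4.04) and Nckap1 (3.92) had higher needle-like effects, with Adora2a and Ces1c below background on all needle-like controls and Adora2a also with MW4 and its control. Cth, which makes cysteine, had log2 changes of 2.59 with MW4, 0.54 with MW3, 0.29 (not passing) with MW2 and -1.25 with MW1, where 2 of 4 arrays were well above background (difference -2.05, SE 0.21). Cdkl4 (-2.5), Mpzl2 (-2.47), Cyyr1 (-2.38) and Or2h15 (-2.19) also had lower needle-like effects, the last 3 with at least 1 group below background on all 4 arrays. NF-kB genes had higher needle-like effects in 20 of 24 cases and lower in 2 (median difference 0.9, adjusted p = 2.99e-17), chemokines and cytokines in 20 of 31 and 1 (median 1.03, adjusted p = 5.59e-15), and cholesterol synthesis genes in 2 and 18 of 24 (median -0.53, adjusted p = 3.57e-11). DNA replication genes fell more with needle-like materials, 25 of 30 lower and none higher with limma (0 at an unadjusted p under 0.05; median -0.37, adjusted p = 3.11e-11). With normexp background 9 of the 10 differences were smaller by over 1.5 times (Mmp9 3.3, Adora2a 1.61, Cth -1.31), with the mean of a gene's probes Mpzl2 did not pass (-0.95), Ces1c was 2.18, Adora2a 3.99 and Cyyr1 -1.62, and Cyyr1 missed the threshold with quantile normalization, with no filter on dim probes, in a fit of only the arrays compared and without MW2 control array 3, MW2 array 1 or 4, MW3 control array 2 or MW3 array 2 or 3 (-2.24 to -1.62). Each experiment had its own scan day, so differences between experiments cannot be told apart from days. The needle-like experiments alone used the older extraction software, so a needle-like difference cannot be told apart from one of version.

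**Figure D3:**
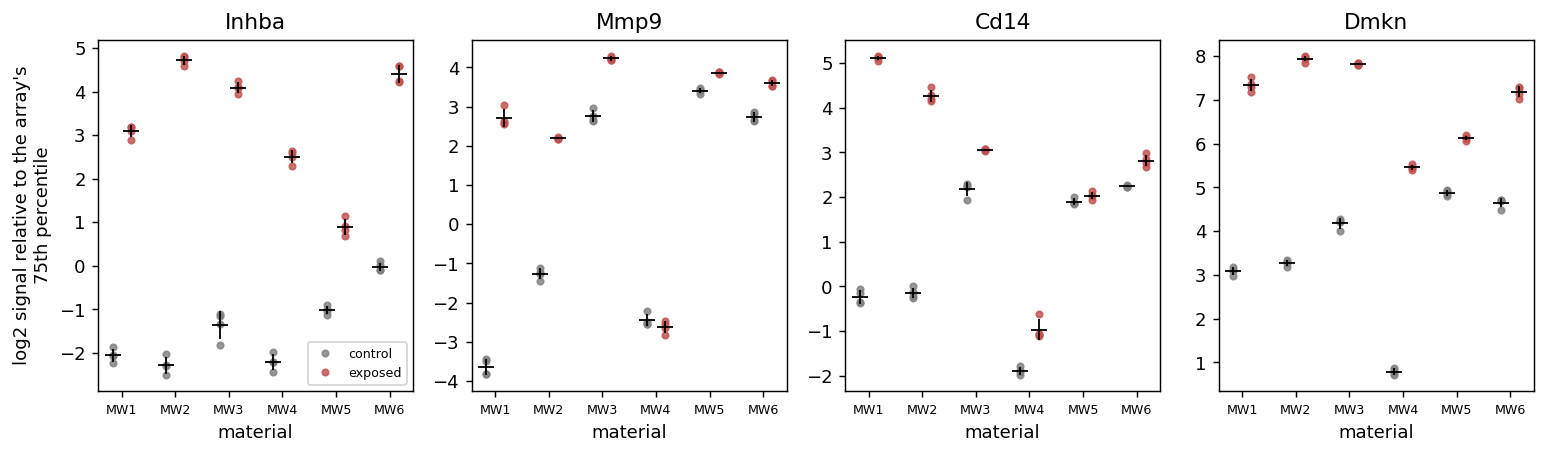
Log2 signal relative to the array's 75th percentile of Inhba, Mmp9, Cd14 and Dmkn on each array, with controls in grey and exposed cells in red for each material. Horizontal lines are means and vertical lines SDs (n = 4 arrays). The log2 change of Cd14 was 5.36 with MW1 and 0.15 with MW5, which did not pass, and the Mmp9 control levels lay between -3.65 and 3.41.

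Thin straight materials were given at 50 µg/mL and others at 100 µg/mL, so shape cannot be told apart from dose. Thin minus needle-like effects differed at 9828 genes, 5467 higher and 4361 lower, but 649 and 1204 at 2-fold. The lectin Clec10a had log2 changes of -2.79 and -3.36 with MW1 and MW2 against -0.16 and -0.85 with MW5 and MW6, of which that with MW5 did not pass (difference 2.58, SE 0.1, adjusted p = 7.65e-23), and Sucnr1 (2.79), Afdn (2.68) and Spata46 (2.64) also had higher thin effects, with all 3 below background on all MW2 arrays and Spata46 on all MW1 arrays. Grin2c (2.25) has no measured thin effect, since its probe was well above background on 1 MW6 array and no other thin or thin control array. The oxidized lipoprotein receptor Olr1 (-5.74), Ces1c (-5.52), Acod1 (-5.37), Adora2a (-5.35) and Nckap1 (-5.15) rose more with needle-like materials, whose controls had all but Nckap1 below background. All were well above it in thin controls (Acod1 on 3 of 4 MW5 ones), so baselines differed. NF-kB genes had lower thin effects in 19 of 24 cases and higher in 3 (median -1.24, adjusted p = 4.48e-13), and DNA replication genes higher ones in 30 of 30 (median 0.96, adjusted p = 2.67e-20). Thin minus bent effects differed at 6285 genes, 3494 higher and 2791 lower (369 and 332 at 2-fold), but 2554 and 2894 with normexp background. Rgcc, a cell cycle regulator, rose by 2.98 and 4.49 with MW3 and MW4 and by 0.24 and 1.47 with MW5 and MW6 (difference -2.88, SE 0.07, adjusted p = 9.84e-29), and the chemokine Ccl12 had -1.63 and -2.64 against 0.23, which did not pass, and 1.08 (difference 2.79, SE 0.14). Slc36a2 (2.59), Angptl4 (2.13), Sucnr1 (2.07) and Pde9a (1.99) had higher thin effects, and Slc6a3 (-3.24), Cdkl4 (-2.88), Col6a5 (-2.71) and Kiaa1671 (-2.68) lower ones. Of these, Slc36a2 was below background on all MW4 arrays, Pde9a on all MW3 arrays and Slc6a3 on all bent controls, and Sucnr1 with MW3, Pde9a with MW6 and Kiaa1671 in the MW4 control were well above it on 1 of 4 arrays. Cholesterol synthesis genes had lower thin effects in 19 of 24 cases and, with limma, none higher (0 at an unadjusted p under 0.05; median -0.42, adjusted p = 1.09e-14), and for chemokines and cytokines the median difference was -0.08 (adjusted p = 0.726). With normexp background 9 of 10 differences in each comparison were smaller by over 1.5 times (Olr1 -2.42, Slc6a3 -1.86) and Pde9a (0.42) did not pass, and with the mean of a gene's probes Afdn was 1.11, Ces1c -3.14, Adora2a -4.45 and Kiaa1671 -0.83.

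The 6 responses shared many genes. Log2 changes correlated across genes, which are not independent replicates, with a median Pearson r of 0.563 over the 15 pairs of materials, from 0.135 (MW1 and MW5) to 0.745 (MW1 and MW2, Spearman rho 0.689). With all 6 materials 392 genes were higher, against 0.303 for independent lists, and 60 were lower, against 0.176. Of these, 28 were at least 2-fold higher with all 6, among them Inhba, Mmp10, Sbsn, Xirp1, Dmkn, Serpinb2 and also Acod1, Hk1 and Slc6a3, whose changes with MW5 did not pass with normexp background (0.41, 0.44 and 0.64), and with limma 0 were at least 2-fold lower with all 6, also at an unadjusted p under 0.05. With normexp background 115 genes were higher and 12 lower with all 6, and other counts are given below. The count of lower genes was 38, 33 and 37 without MW5 control arrays 1, 2 and 4, 34 and 35 without MW5 arrays 3 and 4, and 91 without MW6 array 4.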

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

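The tests without MW5 array 3, of MW5 against the response shared by the other 5 materials and of correlation over bright genes were chosen only after the result was seen, the others before it.

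MW5 changed 811 genes and MW6 7699 at the same dose, and their effects differed at 4348 genes. Without the dim MW5 array 3 the MW5 count was 741, which argues against that array alone having hidden the changes. Array weights gave 2268 genes for MW5 and 6674 for MW6, so the gap's size depends on the fit. The spike-in slope of the MW5 experiment was 1.04 times that of the MW6 experiment (SDs 0.021 and 0.0473, from 4 usable of 10 spike-in probes, against the MW6 experiment's mean levels since amounts were not known, with MW6 array 4 lowest at 0.888), which argues against a compressed signal range. Of 241 genes at least 2-fold higher with the other 5 materials 226 had a positive log2 change with MW5 (median 0.45), and of 95 lower ones 89 had a negative one (-0.25), which is 93.8% together. Direction thus makes a weaker form of the same response a candidate. MW6 helped select these genes, so sizes were not compared with it. Whether this lies in the material, in the dose the cells took up or in the slides was not tested.

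Cholesterol synthesis genes rose as a group with 5 materials (medians 0.39 to 1.1) and not with MW1 (median 0), and the MW1 effect was below the MW2 effect (median difference -0.65, adjusted p = 2.16e-22, 21 of 24 genes lower). Leaving out any 1 of the 8 arrays brought the MW1 median to at most 0.05, which argues against a single array. The higher of the medians under normexp background and quantile normalization was 0, which argues against scaling. The MW1 control's level was -0.32 relative to the median of the other 5 controls, so it was not raised against most of them, but control levels ranged from -1.05 (MW2) to 0.8 (MW4) and exposed ones, likewise relative to the others, were -1.07 (MW1) and -0.69 (MW2), so the difference from MW2 lies at least partly in the controls. A difference between MW1 and the other materials may remain, and an effect of the MW1 slides or day stays open.

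Each group lay on its own slide, so a slide shift and a material's effect cannot be told apart in any 1 comparison. If independent shifts of single slides had made the calls, the 6 responses should be unrelated. Their median correlation over the 15 pairs was 0.646 across 13492 genes well above background on all arrays, from 0.155 to 0.866, which argues against independent shifts as the whole cause. A shift that the exposed slides share could still add to every comparison. The dose and the material, which the design names, remain among the explanations and were not tested apart.

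Among splits of the same arrays, only the real one keeps slides whole for the 6 materials, so slide shifts stay open. Of 35 splits only the real one gave as many genes with MW1 (11230, highest other split 4784), MW2 (11520, 4892), MW3 (9813, 3620), MW4 (8788, 3423), MW5 (811, 4) and MW6 (7699, 3035). The same held for MW1 minus MW2 (4715, 3), MW3 minus MW4 (3567, 1) and MW5 minus MW6 (4348, 10), where exposed arrays were taken relative to their own control's mean before they were split. For the class contrasts 1 of 100 splits of single arrays, the real one, was as large: needle-like minus bent (7283, 4703), thin minus needle-like (9828, 6248) and thin minus bent (6285, 4296). Arrays of 1 experiment are not independent members of a class, and splits of whole experiments gave 3530 and 4703, 5664 and 2315, and 4296 and 3690 genes for these 3 contrasts. Only 3 such splits exist for each, the real one included, too few for a share under 0.05.

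Chance would set an array apart in about 1 in 20 groups, and 4 of 36 tests of array measures and 10 of 180 tests of gene levels did so. MW5 array 3 had 18249 probes well above background (others 22855 to 23256) and a mean correlation of 0.9748 with its group (others 0.9824 to 0.9828). MW6 array 4 had a mean correlation of 0.9184 (others 0.9672 to 0.9676), and MW6 control array 1 had 0.9829 (others 0.9883 to 0.9888). Among log2 levels, Spata46 was -5.6 on MW1 array 4 (others -5.24 to -5.18) and Xirp1 4.18 on MW3 array 4 (4.05 to 4.07). MW3 control array 1 stood apart for Xirp1 at -0.64 (-1.25 to -1.16), Afdn at 0.29 (0.54 to 0.58) and Clec2l at 2.15 (1.81 to 1.86). Fos was 0.38 on MW5 array 4 (0.78 to 0.83), Slc4a8 -1.67 on MW6 array 2 (-1.8 to -1.79) and Abcd2 -2.74 on MW6 array 4 (-2.49 to -2.45). Of the MW6 controls, array 4 had Mpzl2 at -8.13 (-7.12 to -6.95) and array 1 Slc46a3 at -0.29 (-0.4 to -0.38).

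Effects that differed between materials in limma's test of the difference itself are listed here as log2 differences. MW1 minus MW2 was positive for Afdn (3.63), Acss1 (3.51), Prr15 (3.21), Mmp9 (2.89) and Tm4sf20 (2.62) and negative for Arc (-5.04), Rhpn2 (-4.97), Slc35e4 (-3.86) and Cd86 (-2.95). MW3 minus MW4 was positive for Trim63 (4.43), Neu2 (3.95), Arc (3.86), Ablim1 (3.56) and Cd22 (3.54) and negative for Ccn5 (-3.81), Stk32a (-3.19), Scd2 (-3.14), Tph1 (-3.14) and Nos3 (-2.82). MW5 minus MW6 was positive for Sucnr1 (2.46), Afdn (2.3), Coq8a (1.83), Slc36a2 (1.79) and Abcd2 (1.74) and negative for Mpzl2 (-4.6), Slc4a8 (-3.45), Stmn4 (-3.3), Eef1a2 (-3.3) and Vwa2 (-3.18). Needle-like minus bent was positive for Adora2a (4.74), Mmp9 (4.26), Ces1c (4.04), Cd14 (3.99) and Nckap1 (3.92) and negative for Cdkl4 (-2.5), Mpzl2 (-2.47), Cyyr1 (-2.38), Or2h15 (-2.19) and Cth (-2.05). Thin minus needle-like was positive for Sucnr1 (2.79), Afdn (2.68), Spata46 (2.64), Clec10a (2.58) and Grin2c (2.25) and negative for Olr1 (-5.74), Ces1c (-5.52), Acod1 (-5.37), Adora2a (-5.35) and Nckap1 (-5.15). Thin minus bent was positive for Ccl12 (2.79), Slc36a2 (2.59), Angptl4 (2.13), Sucnr1 (2.07) and Pde9a (1.99) and negative for Slc6a3 (-3.24), Rgcc (-2.88), Cdkl4 (-2.88), Col6a5 (-2.71) and Kiaa1671 (-2.68). Most of these include a group well above background on at most 1 of 4 arrays, so their sizes are not exact. With normexp background 12 of them did not pass, among them the 5 positive differences of MW3 minus MW4 (0.13 to 0.54).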

How the results depend on the processing

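Leaving out MW5 array 3 and MW6 array 4 together was chosen after the data were seen, and every other alternative here before it. Of 545 log2 fold changes under the naming rule, 455 kept their direction and their side of the threshold in every alternative run, 84 missed the threshold with the same direction in at least 1, and 7 (1 of them also in the 84) reversed with normexp background, where 5 missed it too. Of 60 named differences, 42 kept both and 18 missed the threshold in at least 1. With normexp background 170 of the 545 fold changes and 55 of the 60 differences moved by over 1.5 times, all to a smaller size. Its offset compresses dim signals by construction, so signal over background limits the size, more than the direction, of changes in genes with a group near background. The fold changes that kept their direction and missed the threshold numbered 65 with normexp background, 17 with quantile normalization, 15 with no filter on dim probes, 23 with the mean of a gene's probes, 18 in a fit of only the arrays compared and 7 with array weights, and 0 with trend and robust variance or the authors' values. For the differences these numbers were 12, 1, 2, 3, 3 and 0. Of 168 tests of a list with a material, 19 calls were lost with an estimated correlation, 8 with normexp background, 4 with quantile normalization and 1 with the mean of a gene's probes, and 6, 6 and 2 were gained with these last 3 and 5 with no filter. Fry, which asks whether a list's genes move one way on balance without comparing them with other genes, gained 58 calls and lost 1.

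With normexp background MW4 gave 13922 genes (6479 of the 8788 shared), MW5 194 (186 shared), MW6 4702 (4583 shared), MW1 minus MW2 2504 and MW5 minus MW6 1933. The median correlation was 0.573, and 115 genes were higher and 12 lower with all 6 materials. Array weights gave 2268 genes for MW5 (801 of the 811 shared) and 6729 for MW3 minus MW4. A fit of only the 8 arrays gave 4512 for MW6 (4185 shared), and 91 genes were lower with all 6 under quantile normalization. With no filter on dim probes the median correlation was 0.43 and 35 genes were lower with all 6. The cause was not tested for any of these. Normexp background moved the median log2 change of all genes from -0.044 to 0.0749 for MW1, -0.0829 to 0.03 for MW3, -0.0268 to 0.257 for MW4, -0.0379 to -0.196 for MW3 minus MW4, -0.0249 to 0.0835 for MW5 minus MW6, -0.00723 to -0.118 for needle-like minus bent and 0.0716 to -0.126 for thin minus bent. Quantile normalization moved it from 0.0495 to -0.0896 for MW6. Relative to the median of 0.257, the log2 changes with MW4 that reversed to positive under normexp background were below it for Lef1 (0.18), Apoa4 (0.1), Gsta4 (0.24) and Ulk1 (0.18) and above it for Cp (0.28), Mx2 (0.53) and Gbp5 (0.48). The oxidative phosphorylation list with MW3 reversed to -0.18 under quantile normalization. The cause of the reversals was not tested beyond this shift.

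At a threshold of at least 2-fold, which by construction counts fewer genes, 2626 genes passed with MW1, 3326 with MW2, 1980 with MW3, 1598 with MW4, 73 with MW5 and 1153 with MW6. The differences counted 1011 (MW1 minus MW2), 548 (MW3 minus MW4), 716 (MW5 minus MW6), 1100 (needle-like minus bent), 1853 (thin minus needle-like) and 701 (thin minus bent), and 28 genes were higher and 0 lower with all 6.

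Without each array in turn the counts ran from 10447 to 10908 (MW1), 10869 to 11131 (MW2), 9101 to 9461 (MW3), 8191 to 8565 (MW4), 468 to 741 (MW5) and 6875 to 7873 (MW6). For the differences the ranges were 4177 to 4658 (MW1 minus MW2), 3094 to 3666 (MW3 minus MW4), 3640 to 4643 (MW5 minus MW6), 6969 to 7356 (needle-like minus bent), 9490 to 10066 (thin minus needle-like) and 5973 to 6498 (thin minus bent). The median correlation ran from 0.526 to 0.568, genes higher with all 6 from 262 to 492 and genes lower with all 6 from 33 to 91. Without MW5 array 3 and MW6 array 4 together the counts were 1038 (MW5), 7127 (MW6), 3956 (MW5 minus MW6), 10025 (thin minus needle-like) and 6511 (thin minus bent), with a median correlation of 0.563 and 422 genes higher and 68 lower with all 6.

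With a replicate block the counts were 11288, 11592, 9867, 8853, 823 and 7725 from MW1 to MW6, and 6 named fold changes and 1 difference missed the threshold. Correlations between exposed and control arrays of the same replicate number, after removing group means, were at most 0.167, and not every array correlated best with its own number, so the numbers are not read as pairs.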

Other observations

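Values below are given in the order MW1 to MW6 unless a material is named, and the test of the NF-kB genes against a scaled bent response was chosen only after the result was seen. Lysosome genes rose in 19, 22, 22, 20, 4 and 11 of 30 cases and fell in 2, 4, 2, 2, 0 and 6 (medians 0.42, 0.45, 0.47, 0.45, 0.14 and 0.14). With MW5, 0 fell in limma, also at an unadjusted p under 0.05. The list passed with 5 materials (adjusted p = 0.000277, 7.15e-05, 3.94e-07, 8.27e-06 and 2.15e-05) and not with MW6 (adjusted p = 0.157), and with an estimated correlation it held with MW3 and MW4 (adjusted p = 0.0206 and 0.0441) and not with MW1, MW2 and MW5 (adjusted p = 0.108, 0.0763 and 0.056). Under normexp background MW4 did not pass (adjusted p = 0.112) and MW6 did (adjusted p = 0.0074). Adjusted over the list alone, 23 genes rose with MW3, 21 with MW4, 6 with MW5 and 12 with MW6. Atp6v0d2, a subunit of the proton pump that acidifies lysosomes, rose 3.65-, 2.65-, 2.55- and 3.19-fold with MW1 to MW4, and the protease cathepsin L (Ctsl) 3.66-fold with MW4. Unfolded protein and amino acid response genes rose in 15, 18, 18, 19, 1 and 15 of 26 cases and fell in 5, 3, 3, 2, 0 and 1 (medians 0.21, 0.59, 0.51, 0.71, 0.09 and 0.22; adjusted p = 0.000587, 9.61e-06, 1.13e-08, 2.96e-11, 0.0189 and 2.79e-06). For MW5, 0 fell at an unadjusted p under 0.05. The estimated correlation kept MW3 and MW4 (adjusted p = 0.0175 and 0.00531) and lost MW1, MW2, MW5 and MW6 (adjusted p = 0.177, 0.0703, 0.41 and 0.0535), and MW5 also failed with normexp background (adjusted p = 0.514) and quantile normalization (adjusted p = 0.342). Over the list alone 19 rose with MW3 and 4 fell with MW2. The stress-induced transcription factor Atf3 rose 5.16-, 10.9-, 6.12-, 5.71-, 1.36- and 4.06-fold and Ddit3, or CHOP, 5.52-fold with MW4.

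Immediate early genes rose in 12, 13, 11, 9, 1 and 11 of 23 cases and fell in 4, 4, 5, 6, 4 and 4 (medians 0.38, 0.56, 0.26, 0.09, -0.03 and 0.39; adjusted p = 0.000616, 0.00251, 0.11, 0.495, 0.0535 and 0.0191). With an estimated correlation MW1 and MW2 held (adjusted p = 0.0131 and 0.026) and MW6 did not (adjusted p = 0.0867), and MW5 passed in the direction down with normexp background (adjusted p = 0.000682), quantile normalization (adjusted p = 0.01) and no filter (adjusted p = 0.00434). Over the list alone 7 fell with MW4, and 12 rose and 5 fell with MW6. The transcription factor Maff rose 12.9-, 21.3-, 7.13- and 8.22-fold with MW1 to MW4 and 3.69-fold with MW6 (log2 1.98, 2.95, 1.91, 1.49 and 0.98 with normexp background), whereas Fos was 4.17-fold lower with MW3 and 3.56-fold with MW6. Genes of LXR targets and lipid storage went both ways, with 6, 8, 9, 10, 2 and 3 of 18 higher and 5, 7, 3, 6, 1 and 6 lower (medians 0.14, 0.14, 0.27, 0.21, 0.07 and -0.05; adjusted p = 0.484, 0.873, 0.125, 0.112, 0.457 and 0.487). Over the list alone 7 rose with MW1, 9 with MW2 and 3 with MW5, where 2 fell. The fatty acid carrier Fabp4 rose 5.48-, 8.87-, 7.59-, 10.4-, 1.49- and 4.24-fold (with MW5 not past the threshold under normexp background), while Angptl4 was 2.3-, 5.33-, 6.04- and 8.26-fold lower with MW1 to MW4 (log2 -1.66 with MW3 and -1.08 with MW4 under normexp background).

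NRF2 oxidative stress genes rose in 15, 10, 11, 8, 5 and 4 of 26 cases and fell in 7, 8, 9, 8, 0 and 9 (medians 0.27, 0.08, 0.2, -0.02, 0.06 and -0.08; adjusted p = 0.128, 0.873, 0.487, 0.982, 0.0149 and 0.309). The MW5 call was lost with an estimated correlation (adjusted p = 0.158), MW6 passed with no filter (adjusted p = 0.0421), the mean with MW3 was 0, and with MW4 the mean was -0.01 and the test's direction up. Over the list alone 9 rose and 9 fell with MW4 and 6 and 1 with MW5, where 1 fell at an unadjusted p under 0.05. Heme oxygenase 1 (Hmox1) rose 2.51-, 2.06-, 2.09- and 1.29-fold with MW2 to MW5, and Ephx1 was 2.54-, 1.97-, 2.48- and 1.91-fold lower with MW1 to MW4. Metal and iron genes rose in 9, 8, 6, 4, 2 and 5 of 19 cases and fell in 2, 2, 3, 4, 0 and 3 (medians 0.3, 0.17, 0.15, 0.07, 0 and 0.13; adjusted p = 0.0608, 0.0848, 0.309, 0.815, 0.375 and 0.935). MW1 passed with the mean of a gene's probes (adjusted p = 0.0157), and MW2 with it and with no filter (adjusted p = 0.0152 and 0.0301). With MW5 the mean was -0.01 and the direction up, 2 fell at an unadjusted p under 0.05, and 3 rose and 1 fell over the list alone. With MW6 the mean was 0 and the direction down. The phagosomal metal transporter Slc11a1 rose 4.75-, 3.55-, 1.99-, 2.48- and 1.29-fold with MW1 to MW5. Autophagy genes rose in 9, 11, 13, 8, 4 and 5 of 20 cases and fell in 2, 4, 1, 2, 0 and 1 (medians 0.1, 0.28, 0.45, 0.16, 0.12 and 0; adjusted p = 0.1, 0.116, 1.77e-05, 0.0424, 0.00119 and 0.462), with 0 lower at an unadjusted p under 0.05 with MW5. With an estimated correlation MW3 and MW5 held (adjusted p = 0.00291 and 0.0239) and MW4 did not (adjusted p = 0.161), and under normexp background MW4 and MW5 failed (adjusted p = 0.913 and 0.107). Over the list alone 3 fell with MW1 and 6 rose with MW5. The cargo receptor Sqstm1 rose 2.12-, 2.01-, 2.8- and 2.88-fold with MW1 to MW4.

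Scavenger and phagocytic receptor genes rose in 11, 9, 9, 9, 0 and 6 of 18 cases and fell in 6, 8, 6, 6, 0 and 5 (medians 0.24, 0.16, 0.16, 0.08, 0.06 and -0.02; adjusted p = 0.0131, 0.442, 0.688, 0.745, 0.696 and 0.484), with adjusted p = 0.271 for MW1 with an estimated correlation. With MW5, 4 rose and 1 fell at an unadjusted p under 0.05, and 3 and 1 over the list alone, which gave 7 rises with MW6. Cd14 rose 41-fold with MW1 and 21.4-fold with MW2, Clec4e, a receptor for mycobacterial glycolipid, was at least 38.6-fold higher with MW1 (log2 3.22 with normexp background), and Tlr4, the lipopolysaccharide receptor, was 2.31- and 3.43-fold lower with MW3 and MW4. Heat shock genes rose in 6, 8, 8, 3, 1 and 4 of 17 cases and fell in 5, 3, 2, 5, 0 and 1 (medians 0.19, 0.24, 0.1, 0, 0.1 and 0.1; adjusted p = 0.302, 0.125, 0.00954, 0.832, 0.0179 and 0.278), with 0 lower at an unadjusted p under 0.05 with MW5 and 8 higher over the list alone with MW1. The calls with MW3 and MW5 were lost with an estimated correlation (adjusted p = 0.237 and 0.288), normexp background (adjusted p = 0.0762 and 0.112) and quantile normalization (adjusted p = 0.0601 and 0.115), and that with MW5 with the mean of a gene's probes (adjusted p = 0.0939). The small chaperone Hspb1 rose 2.96-, 10.1-, 9.12-, 5.76-, 2.13- and 8.9-fold. Of 17 p53 targets 7, 7, 5, 6, 0 and 3 rose and 6, 8, 7, 6, 0 and 6 fell (medians -0.03, -0.03, 0, -0.08, 0.03 and -0.06; adjusted p = 0.734, 0.745, 0.879, 0.593, 0.873 and 0.752), with 3 higher and 2 lower at an unadjusted p under 0.05 with MW5. The means with MW1, MW2, MW4 and MW6 were 0.08, 0.15, 0.2 and 0.01. The growth arrest gene Gadd45a rose 3.28-, 3.67-, 8.26- and 2.59-fold with MW2, MW3, MW4 and MW6. Interferon response genes rose in 11, 8, 3, 4, 0 and 1 of 26 cases and fell in 3, 10, 12, 11, 0 and 9 (medians 0.25, -0.03, -0.24, -0.16, -0.12 and -0.29; adjusted p = 0.145, 0.672, 0.167, 0.234, 0.0056 and 0.00441). The calls with MW5 and MW6 were lost with an estimated correlation (adjusted p = 0.414 and 0.412), MW3 passed with no filter (adjusted p = 0.0299), and 0 rose and 4 fell at an unadjusted p under 0.05 with MW5. The interferon-induced GTPase Ifi47 was 2.55-, 4.76-, 3.94-, 3.06- and 2.69-fold lower with all but MW5.

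Oxidative phosphorylation genes rose in 3, 3, 2, 1, 0 and 1 of 24 cases and fell in 12, 9, 3, 10, 0 and 2 (medians -0.18, -0.1, 0.03, -0.1, 0.07 and 0.01; adjusted p = 0.116, 0.505, 0.947, 0.296, 0.217 and 0.982), with 2 lower with MW3 over the list alone. With MW5, 2 rose and 1 fell at an unadjusted p under 0.05 and the mean was 0, and with MW6 the mean was 0.03 and the direction down. The list passed downward with MW1 under normexp background, quantile normalization and no filter (adjusted p = 0.0345, 0.00658 and 0.00634), with MW2 and MW3 under quantile normalization (adjusted p = 0.0358 and 0.0429) and with MW4 under normexp background and quantile normalization (adjusted p = 8.67e-05 and 0.0331). Antigen presentation genes rose in 5, 2, 3, 2, 0 and 3 of 13 cases and fell in 3, 8, 6, 8, 0 and 5 (medians -0.09, -0.22, -0.25, -0.34, 0.04 and -0.14; means with MW2 and MW6 0.17 and 0.15; adjusted p = 0.919, 0.365, 0.12, 0.0161, 0.982 and 0.245). The call with MW4 was lost with an estimated correlation (adjusted p = 0.109), MW3 passed with quantile normalization (adjusted p = 0.0316), 9 fell with MW4 and 1 rose with MW5 over the list alone, and 1 and 0 rose and fell with MW5 at an unadjusted p under 0.05. The costimulatory Cd86 was at least 4.36-fold higher with MW2 (another probe 0.34, normexp background 0.99 on the log2 scale), Cd40 rose 3.57-fold with MW2 (0.96 with normexp background), and RT1-DMa, which loads class II molecules, was 2.04- and 2.15-fold lower with MW3 and MW4. Macrophage identity genes rose in 7, 6, 5, 2, 1 and 4 of 22 cases and fell in 3, 6, 7, 6, 0 and 6 (medians 0.05, 0, -0.24, 0.07, 0.05 and -0.02; adjusted p = 0.477, 0.997, 0.721, 0.595, 0.866 and 0.638). The mean was -0.16 with MW4, 0 with MW5 and 0.1 with MW6, 1 fell at an unadjusted p under 0.05 with MW5, and 6 rose with MW1 and 5 with MW6 over the list alone. The carbonic anhydrase Car4 rose by a log2 of 5.5 with MW1, with 1 of 4 control arrays well above background, and was at least 13.9-fold higher with MW2 (2.77 and 2.09 with normexp background). The growth factor receptor gene Csf1r was 2.99-, 3.49- and 4.48-fold lower with MW2, MW3 and MW4, whereas its other probe gave log2 changes of -0.11, 0.05 and -0.3, and with the mean of both it did not pass with MW2 and MW3.

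Among markers of other cell types no list passed in a comparison of a material with its control. The lists held 7 genes of epithelium, 6 of fibroblasts and smooth muscle, 4 each of endothelium, lymphocytes, and neutrophils and mast cells, and 1 erythroid gene, and the lowest adjusted p was 0.139 (fibroblasts and smooth muscle with MW5). With each material at most 4 genes of a list rose and at most 3 fell. Single members still moved, with the proteoglycan Dcn 2.06-, 2.93-, 2.28-, 3.38-, 1.37- and 1.41-fold higher, the membrane protease Fap 2.26-, 2.38-, 3.5-, 3.25-, 1.28- and 1.95-fold lower, the antimicrobial peptide gene Camp 6.4-fold higher with MW1 and the cytotoxic granule gene Nkg7 3.58-fold lower with MW3. Of 13 reference genes 6, 7, 7, 5, 2 and 3 rose and 3, 3, 2, 2, 0 and 1 fell (medians 0.06, 0.23, 0.34, 0.1, 0.08 and 0.1; adjusted p = 0.545, 0.208, 0.0299, 0.302, 0.145 and 0.433). The call with MW3 was lost with an estimated correlation (adjusted p = 0.331), normexp background (adjusted p = 0.0877) and quantile normalization (adjusted p = 0.32), 8 rose with MW3 over the list alone, and with MW5 3 rose and 1 fell there and at an unadjusted p under 0.05.

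A hypothesis was that needle-like materials raised NF-kB genes more than bent ones because they gave a larger response of the same make-up. Multiplied by 1.27, the ratio of the SDs of the needle-like and bent responses across genes, the bent effects still left a median of 0.87 over the 24 NF-kB genes, whose medians were 1.59 with needle-like and 0.38 with bent materials. Chemokines and cytokines kept 0.95 and cholesterol synthesis genes -0.81, whereas mitosis genes kept -0.09, DNA replication and lysosome genes -0.15, glycolysis genes -0.13 and matrix genes 0.01. The cholesterol synthesis medians with MW1 to MW4 were 0, 0.86, 1.1 and 0.88, so -0.81 rests mainly on MW1. The NF-kB and chemokine values argue against a common scale. For these genes the classes may differ in make-up, with days, slides and software version, which also separates the classes, still open.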
